A study of Mus musculus with 17 samples.

How the data were processed

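RNA was measured by sequencing in 16 mouse libraries, 2 for each of 8 group codes. Per the labels' protocols, ribosomal RNA was depleted enzymatically (RNase H, RiboErase), the rest was fragmented by heat and copied into cDNA from random hexamers, and the amplification primers carried unique dual indexes. The labels also name the molecule as polyA RNA. A 17th labelled sample, with the code ESF, is not analysed here. Per the submitters' processing notes, the tools were cutadapt 2.7, FastQC 0.11.4, STAR 2.5.4 and featureCounts of Subread 1.6.3, with the mouse genome build mm10. The notes give these names without order or settings. The strand setting, the annotation release and any filter on genes are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and members of gene families, such as immunoglobulin segments and the Serpina1 paralogs, may share reads.

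The authors deposited 1 table of CPM values, reads of a gene scaled so that a library sums to 1000000, for 54658 genes by symbol. Each column summed to 1000000, so no further scaling had been applied between libraries. All nonzero values were whole multiples of the value of 1 read (100%, tolerance 0.001 reads), which returned the read counts. Totals ranged from 16444965 to 25805502 reads, and 1 read was worth 0.039 to 0.061 CPM. A count of 0 allows up to 3 reads, so a fold against a side with 0 reads is given as a lower bound from 3 reads summed over that side. Where a side had 1 to 3 reads, the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Genome positions are those of mm10 in the GENCODE M21 annotation, which holds 54106 of the symbols (99%).

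Groups were taken from the codes in the labels. Comparisons were made between equally weighted means of the groups. KO implants (MKM, MKF) were compared with WT implants (MWM, MWF), together, within the groups described as male and within those described as female, and by the difference between these. Male implant groups were compared with female ones, visceral fat (EVM, EVFY, EVFN) with subcutaneous fat (ESM), WT implants with each of these, and EVFY with EVFN. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Chi-square statistics of the read counts within a group were 24.7 to 240 per degree of freedom, so the libraries of every group differed by more than sampling noise.

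The test was limma (3.58.1, R 4.3.3) with a mean-variance trend and robust empirical Bayes on log2(CPM + 0.5), for the 17964 genes with at least 1 CPM in at least 2 libraries. All 8 groups entered 1 model of group means with 8 residual degrees of freedom. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to rise or fall. A set of 29 gene lists was tested with camera (lists with at least 5 tested genes) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 203 tests of a list in a comparison, 104 passed the threshold with the preset correlation and 0 with the estimated one, and without the libraries labelled EVFN1 and MKM1 these numbers were 115 and 2. Members of a list were also counted with p-values adjusted over the list alone.

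The groups, comparisons, lists, tests and alternatives were fixed before the data were examined, for 17 libraries and 9 groups. With ESF not analysed here, subcutaneous fat is represented by ESM alone. The setting without the libraries labelled EVFN1 and MKM1 was chosen after seeing the data; it tests the same genes with 6 residual degrees of freedom. The organ markers were likewise chosen after seeing the data. Genes are named by a fixed rule. Lep, Lepr and Cfd are always named. For the 4 comparisons of tissues, up to 4 members of each described list with the smallest adjusted p are named, or up to 2 with the smallest p where none passed. Further genes are the 5 rising and 5 falling ones with the largest fold among those past the threshold, with a mean of at least 5 CPM on the higher side, no overlap between the sides and a symbol that is not a predicted gene name. For the other comparisons these were the 3 rising and 3 falling ones. The part of the rule on overlap could not be applied to the difference between sexes. Genes given there are ones named between KO and WT implants, or were chosen after their values were seen. Genes named without both libraries follow the same rule in that setting. A few genes that the rule or a short count would name are not reported here.

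Alternatives were pseudocounts of 0.1 and 2, no filter on low genes, median-of-ratios scaling, array quality weights, the replicate number as a block, a fit of the compared groups alone, visceral fat without EVFN, EVM against ESM alone, each library left out in turn, and edgeR (4.0.16) with its quasi-likelihood test and TMM scaling on the recovered read counts. The limma step was tested on data simulated from the means and dispersions of these libraries. Among 17964 genes, 100 above 5 CPM were changed 2-fold and 100 4-fold. It recovered 43% and 90% of them for KO against WT implants (8 false among 141 calls). For visceral against subcutaneous fat these were 17% and 82% (3 of 102). For WT implants they were 21% and 72% against subcutaneous fat (3 of 96), and 48% and 88% against visceral fat (10 of 146). Recovery may be lower in the real data, where single libraries moved the counts.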

Results

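The series, whose title concerns leptin, complement factor D, osteoarthritis and pain, measured RNA in 16 mouse libraries, 2 for each of 8 group codes. Its design text describes hosts of a type named LD that received mouse embryonic fibroblasts (MEF) from wildtype (WT) or leptin knockout (KO) pups by injection under the skin of the chest at 3 to 5 weeks of age. The cells grew into tissue resembling fat. Surgical animals had the medial meniscus of 1 knee destabilized at 16 weeks, an operation that leads to osteoarthritis, and all ended at 28 weeks. Implants from WT donors carry the codes MWM and MWF and those from KO donors MKM and MKF, where M and F at the end stand for groups described as male and female. Endogenous fat carries the codes EVM (visceral, surgery), EVFN (visceral, no surgery), EVFY (visceral by its genotype label, with the code not spelled out) and ESM (subcutaneous, male, surgery). The text also calls the hosts male. Totals ranged from 16444965 reads (MWF2) to 25805502 (EVM2). The labels name the tissue as ganglia. The mean of 8 adipocyte genes was 1126 to 4442 CPM over the libraries, and that of 11 sensory neuron genes was 0.548 to 6.66 CPM.

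Leptin (Lep, chromosome 6, 29060220 to 29073877, plus strand, mm10), the hormone gene knocked out in the KO donors, was measured at 1045 (MKM1), 1336 (MKM2), 1644 (MKF1) and 1726 CPM (MKF2) in the KO implants. In the WT implants it was 1888 (MWM1), 2675 (MWM2), 806 (MWF1) and 1019 CPM (MWF2). The labels do not give the allele, so this transcript level does not check the genotype. Complement factor D (Cfd, adipsin, chromosome 10, 79890853 to 79892655, plus strand), a serine protease secreted by adipocytes, was at 91.4 (MKF1), 104 (MKF2) and 102 CPM (MKM2) in 3 of the KO implants and at 14070 CPM in the library labelled MKM1. It was at 5788 to 13270 CPM in 7 of the endogenous fat libraries and at 81.8 CPM in the library labelled EVFN1. The mesothelial gene Upk3b (chromosome 5, 136038496 to 136046487, plus strand) was at 200.4 CPM in the library labelled MKM1 and at 0 in MKM2. It was at 0.058 CPM in the library labelled EVFN1 and at 148 in EVFN2. Across genes, the library labelled EVFN1 correlated best with MKF1 (r = 0.984) and less with EVFN2 (r = 0.906). The library labelled MKM1 correlated best with EVFY1 (r = 0.989) and less with MKM2 (r = 0.891). Genes are not independent replicates in these correlations. The count of all genes past the threshold in each comparison is therefore given both with all 16 libraries as labelled and without these 2 libraries. Counts within a list are with all 16 libraries unless stated, and a direction that involves the KO or the visceral groups rests on their labels.

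Genes of the sex chromosomes were read in every library as a further check of the labels. Ddx3y, encoded on the Y chromosome, was at 73.5 to 95.5 CPM in ESM1, ESM2, EVM1, EVM2 and MKM2, where Xist, transcribed from the inactive X chromosome, was at 0.057 to 3.77 CPM. Ddx3y was at 0 CPM in the library labelled MKM1, with Xist at 352 CPM. In MWM1 and MWM2 Ddx3y was at 13.1 and 17.3 CPM and Xist at 494 and 466 CPM, and in the library labelled EVFN1 these values were 29.3 and 278 CPM. EVFY1, EVFY2, EVFN2, MKF1, MKF2, MWF1 and MWF2 had Xist at 273 to 766 CPM and Ddx3y at no more than 0.266 CPM.

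**Figure D1:**
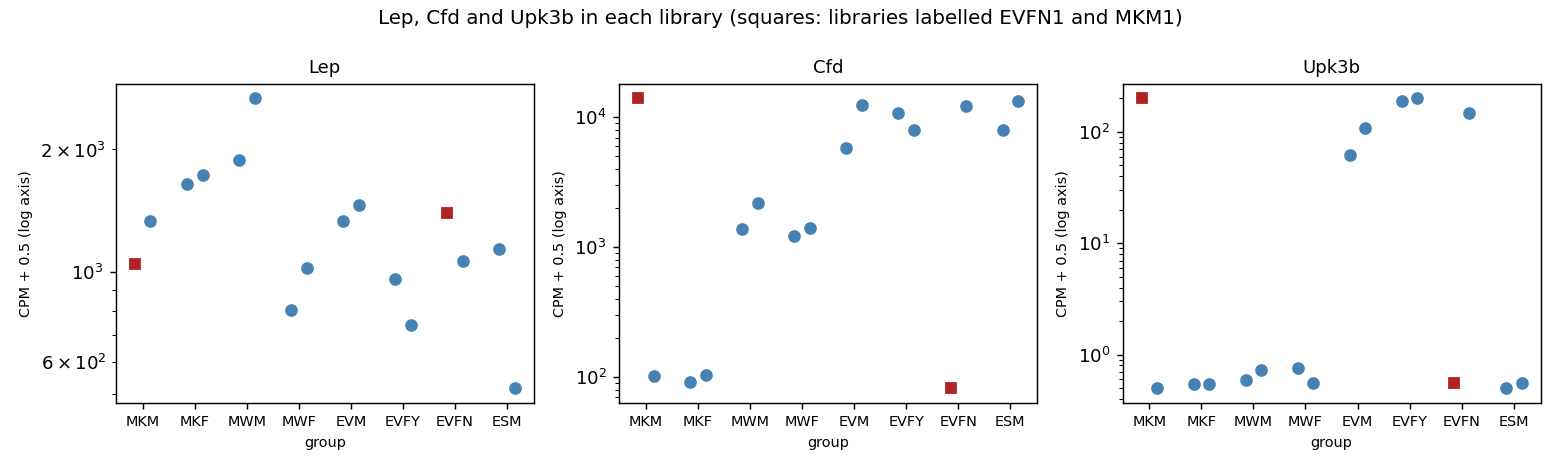
CPM + 0.5 (log axis) of Lep, Cfd and Upk3b in each of the 16 libraries, by group code on the x axis. Red squares are the libraries labelled EVFN1 and MKM1 and blue circles the others. Cfd lies at 81.8 CPM in the library labelled EVFN1 and at 14070 CPM in the library labelled MKM1.

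The first comparison asked how implants from leptin KO donors differed from those of WT donors (4 against 4 libraries). Macrophage genes were higher in the KO implants. Csf1r (chromosome 18, 61100598 to 61132149, plus strand), the receptor for the macrophage growth factor CSF1, was at 632 ± 170 CPM (SD, n = 4) against 198.5 ± 8.83 (n = 4), a log2 fold change of 1.62 (SE 0.27, adjusted p = 0.0279, limma with BH). Siglec1, a sialic acid receptor of tissue macrophages, rose by 2.22 (SE 0.30, adjusted p = 0.0199), Clec10a, a lectin of macrophages and dendritic cells, by 1.45 (SE 0.21, adjusted p = 0.0209) and Cd14, a coreceptor for bacterial lipopolysaccharide, by 1.18 (SE 0.18, adjusted p = 0.0241). Of 25 tested macrophage genes, 7 rose over all genes and 10 rose adjusted over the list alone. Camera gave an adjusted p of 1.76e-08 with the preset correlation and an adjusted p = 0.421 with an estimated correlation. Among 27 complement genes 2 rose, the C5a receptor gene C5ar1 by 2.04 (SE 0.41, adjusted p = 0.0406) and the macrophage complement receptor gene Vsig4 by 2.69 (SE 0.55, adjusted p = 0.043), and 7 rose adjusted over the list alone. Camera gave an adjusted p of 0.00893 for that list, and adjusted p = 0.484 with an estimated correlation. Of 27 genes of fibroblasts and extracellular matrix, 4 rose adjusted over the list alone (Lox, Loxl2, Mmp14 and Postn), with a camera adjusted p of 2.57e-06, and adjusted p = 0.484 with an estimated correlation. The matrix protein gene Postn was at 691 ± 167 against 176 ± 23.8 CPM (adjusted p = 0.0604) and the membrane protease gene Mmp14 at 321 ± 49.8 against 152 ± 21.6 CPM (adjusted p = 0.0561). Pdgfrb, a receptor of mural cells and fibroblasts, rose by 0.93 (SE 0.17, adjusted p = 0.0341). The genes with the largest rises under the naming rule were Ripor3 with 2.30 (SE 0.37, adjusted p = 0.0268) and Folr2, a folate receptor of resident macrophages, with 2.29 (SE 0.40, adjusted p = 0.0321).

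Genes of nerves were lower in the KO implants. Prx (chromosome 7, 27499324 to 27520214, plus strand), periaxin of myelinating Schwann cells, was at 7.64 ± 1.88 against 18.6 ± 3.33 CPM and fell by 1.25 (SE 0.20, adjusted p = 0.0269, limma with BH). Cnp, an enzyme of myelin, had a log2 fold change of -0.63 (SE 0.12, adjusted p = 0.0376), and was lower only than in MWF1 and MWF2, with 102 and 86.5 CPM there, 32.2 and 31.96 CPM in MWM1 and MWM2 and 32.7 to 37.1 CPM in the KO implants. Of 21 genes of satellite glia and Schwann cells, 5 fell over all genes, among them Prx, Cnp and Sox10, and adjusted over the list alone 11 fell and 1 rose (Pmp22). Sox10, Pmp22 and the genes Nefm and Piezo2 below were chosen after their values were seen. Camera gave an adjusted p of 0.00022, and adjusted p = 0.484 with an estimated correlation. Of 19 sensory neuron genes 5 fell (Avil, Nefh, Nefl, Nefm and Th), and adjusted over the list alone 14 fell and 1 rose (Piezo2), with a camera adjusted p of 9.04e-08, and adjusted p = 0.421 with an estimated correlation. These genes were low in all implants. Avil, an actin regulator of sensory neurons, was at 1.19 ± 0.776 against 3.57 ± 0.844 CPM (log2 fold change -1.37, SE 0.18, adjusted p = 0.0199). The neurofilament genes Nefl and Nefh fell by 2.16 (SE 0.39) and 2.27 (SE 0.43), with adjusted p = 0.0345 and 0.037, and Th, the first enzyme of catecholamine synthesis, fell by 1.43 (SE 0.27, adjusted p = 0.0376). Transcripts of some other organs were lower too. Pth (chromosome 7, 113385580 to 113388570, minus strand), parathyroid hormone, had 2 reads over the 4 KO libraries and was at 22.04 ± 5.50 CPM in the WT implants, a ratio of 890 (95% counting interval 246 to 7360, adjusted p = 2.37e-07). Chga, a granule protein of neuroendocrine cells, had a log2 fold change of -4.97 (SE 0.50, adjusted p = 0.0079). Scgb1a1, secreted by airway club cells, fell by 5.91 (SE 0.98, adjusted p = 0.0269), and the lung surfactant gene Sftpb fell by 4.31 (SE 0.86, adjusted p = 0.0396). Serpina1e, a liver protease inhibitor in a family of close copies and so uncertain, fell by 3.85 (SE 0.52, adjusted p = 0.0199). The mean of 6 lung marker genes was 19.97 to 84.7 CPM in the WT implants and 0.0276 to 4.03 CPM in the KO implants. Liver markers did not part the genotypes in this way, with a mean of 8 genes of 298 to 1448 CPM in the WT implants, 1062 CPM in MKM2, 181 in MKF1, 6.30 in MKF2 and 3.45 in the library labelled MKM1.

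Of the other lists, those of lymphocytes, skeletal muscle, mitochondrial respiration and glandular epithelium had few or no members past the threshold over all genes between KO and WT implants. Of 28 T and NK lymphocyte genes 2 fell, Foxp3, the master regulator of regulatory T cells, by 1.10 (SE 0.20, adjusted p = 0.0331, limma with BH) and Cd247, a signalling chain of the T cell receptor, by 1.47 (SE 0.30, adjusted p = 0.0411). Adjusted over the list alone 14 fell and 2 rose (Gzmb and Ncr1), with a camera adjusted p of 1.86e-06, and adjusted p = 0.502 with an estimated correlation. The mean of 4 lymphocyte marker genes was 141 and 88.7 CPM in MWF1 and MWF2, 1.43 and 5.05 in MWM1 and MWM2, and 0.859 to 23.05 in the KO implants. In the male groups Foxp3 was at 0.551 and 1.12 CPM in the library labelled MKM1 and in MKM2 against 0.517 and 0.565 in MWM1 and MWM2, and Cd247 at 3.20 and 6.82 against 4.51 and 3.67 CPM. No B or plasma cell gene of 23 passed over all genes, and 4 fell adjusted over the list alone (Bank1, Cr2, Fcrla and Ighm, camera adjusted p = 0.000188, and adjusted p = 0.537 with an estimated correlation). The complement receptor gene Cr2 was at 1.75 ± 2.05 against 23.6 ± 27.9 CPM (adjusted p = 0.0661) and the IgM constant region gene Ighm at 559 ± 173 against 2224 ± 2494 CPM (adjusted p = 0.0849). None of 24 skeletal muscle genes passed over all genes, and 20 fell adjusted over the list alone (camera adjusted p = 1.38e-07, and adjusted p = 0.582 with an estimated correlation). The myosin light chain gene Myl1 was at 45.5 ± 33.5 against 639 ± 410 CPM (adjusted p = 0.0737). Of 28 genes of mitochondrial respiration, none passed over all genes and 22 fell adjusted over the list alone (camera adjusted p = 2.67e-08, and adjusted p = 0.502 with an estimated correlation). The respiratory chain genes Ndufa4 and Ndufb9 were at 85.3 ± 7.51 against 116 ± 11.6 CPM and 41.5 ± 2.66 against 56.1 ± 3.40 CPM. Among 16 mammary and glandular epithelium genes 1 fell, the transcription factor gene Grhl2 with -1.93 (SE 0.34, adjusted p = 0.0325), and 7 fell adjusted over the list alone (camera adjusted p = 2.72e-05, and adjusted p = 0.484 with an estimated correlation). Lep itself differed by less than the spread (log2 fold change -0.02, SE 0.25, adjusted p = 0.977). Its receptor gene Lepr was at 12.5 ± 7.42 against 21.95 ± 7.71 CPM (log2 fold change -0.93, SE 0.26, adjusted p = 0.084). Lepr was lower only in the female groups (values below). Bank1, Fcrla, Gzmb and Ncr1 were chosen after their values were seen.

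Over all genes, limma counted 309 between KO and WT implants, 123 higher and 186 lower in KO. EdgeR counted 176, with 127 higher and 49 lower, and limma gave 187 higher and 203 lower with median-of-ratios scaling and 49 and 28 with a pseudocount of 0.1, so the split between rises and falls depended on the processing. Pth was kept past the threshold whichever library was left out, as was Chga, alone among the 23 genes named by the rule for this comparison that passed with all libraries. The count was 116 without MWF2, 44 without MWF1, 9 without the library labelled MKM1, 9 without MWM2, 5 without MWM1 (Plau higher, Chga, Crisp1, Pth and Serpina1e lower) and 2 without MKF2 (Chga and Pth). Genes in these short lists were chosen after their values were seen.

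Without the libraries labelled EVFN1 and MKM1, a setting chosen after seeing the data, 1935 genes passed between 3 KO and 4 WT implants, 1198 higher and 737 lower. Macrophage genes then made up a larger set, with 18 of 25 higher and 1 lower (Timd4, chosen after its values were seen, camera adjusted p = 3.74e-13, and adjusted p = 0.21 with an estimated correlation). Gpnmb (chromosome 6, 49036546 to 49070929, plus strand), a glycoprotein of lipid-laden macrophages, was at 1931 ± 97.6 CPM (n = 3) against 157 ± 109 (n = 4), a log2 fold change of 3.86 (SE 0.32, adjusted p = 0.000362, limma with BH). Trem2, a lipid receptor, rose by 3.96 (SE 0.34, adjusted p = 0.000423) and lysosomal Cd68 by 2.85 (SE 0.21, adjusted p = 0.000337). Atp6v0d2, a proton pump subunit, rose by 3.83 (SE 0.27, adjusted p = 0.000337), and Tm4sf19 and Myh15 by 3.86 (SE 0.20) and 4.51 (SE 0.23). Postn and Mmp14 passed in this setting, with adjusted p = 0.0296 and 0.0234. Cfd was at 99.1 ± 6.70 CPM in these KO implants against 1560 ± 442 CPM in the WT implants, a log2 fold change of -3.92 (SE 0.32, adjusted p = 0.000339). With all 16 libraries it was -2.15 (SE 1.6, adjusted p = 0.452), and with the library labelled MKM1 alone left out it was -3.92 (SE 1.35, adjusted p = 0.137). The beta-3 adrenergic receptor gene Adrb3 fell by 3.80 (SE 0.52, adjusted p = 0.00295), the resistin gene Retn by 2.14 (SE 0.41, adjusted p = 0.0142) and the adipocyte carbonic anhydrase gene Car3 by 1.86 (SE 0.27, adjusted p = 0.00367). Of 24 white adipocyte genes 6 fell and 1 rose (Cd36, chosen after its values were seen), and the list as a whole had a camera adjusted p of 0.54. Of 19 sensory neuron genes 10 fell in this setting. Adjusted over the list alone, no gene of mitochondrial respiration fell (camera adjusted p = 7.97e-06, and adjusted p = 0.702 with an estimated correlation), no B or plasma cell gene (camera adjusted p = 0.00852, and adjusted p = 0.753 with an estimated correlation) and 2 mammary and glandular epithelium genes (Esr1, chosen after its values were seen, and Grhl2, camera adjusted p = 0.00204, and adjusted p = 0.544 with an estimated correlation).

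Whether the KO difference varied with sex was tested as the difference between the male and the female groups (2 libraries per group). T cell genes led it. The T cell receptor chain gene Cd247 had a difference of 3.32 on the log2 scale (SE 0.60, adjusted p = 0.0378, limma with BH), male minus female, and Foxp3 of 2.85 (SE 0.40, adjusted p = 0.0306). Both genes, and Cnp below, are ones named between KO and WT implants. Foxp3 was at 14.1 and 12.3 CPM in MWF1 and MWF2, at 0.517 and 0.565 in MWM1 and MWM2, at 2.27 and 1.54 in MKF1 and MKF2, and at 0.551 and 1.12 CPM in the library labelled MKM1 and in MKM2. Of 28 T and NK lymphocyte genes, 14 passed, all with a positive difference, and 23 passed adjusted over the list alone (camera adjusted p = 7.79e-17, and adjusted p = 0.414 with an estimated correlation). The B and plasma cell list had 17 of 23 adjusted over the list alone (camera adjusted p = 7.3e-07, and adjusted p = 0.517 with an estimated correlation). Thymus markers (mean of 3 genes) were at 86.6 CPM in MWF2 and 6.18 in MKM2, and at no more than 0.266 CPM in the other implants. The myelin gene Cnp had a difference of 1.61 (SE 0.24, adjusted p = 0.0306), with its highest levels in MWF1 and MWF2. In all, 217 genes passed, 216 positive and 1 negative, which was Ltbp3, a binding protein of latent TGF-beta, with -1.47 (SE 0.28, adjusted p = 0.0401), named after its values were seen. With edgeR the adjusted p was 0.12 for each of Cd247, Foxp3, Cnp and Ltbp3. Lep had a difference of -1.82 (SE 0.49, adjusted p = 0.102), Lepr of 2.27 (SE 0.51, adjusted p = 0.0642) and Cfd of 3.21 (SE 3.20, adjusted p = 0.635). The median of all genes was 0.258 in this comparison and 0.027 with median-of-ratios scaling, under which 71 genes passed (68 positive, 3 negative, which were Carhsp1, Lmo1 and Ltbp3).

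Without the libraries labelled EVFN1 and MKM1, 101 genes passed for the difference by sex, 99 positive and 2 negative (Cck and Xist), with MKM2 as the 1 library of its group, assumed to vary like the other groups. With all 16 libraries edgeR counted 0, with 2852 genes at an unadjusted p under 0.05. Of the single libraries left out, MKF1 gave 283, MWF1 21, the library labelled MKM1 19, MWF2 2 (Akna and Sst), MKF2 1, MKM2 1 (Ighv1-15), and MWM1 and MWM2 gave 0 each in limma, with 2498 and 1991 genes at an unadjusted p under 0.05. In each of these fits 1 of the 4 groups held 1 library. All genes named here were chosen after their values were seen.

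Within the male groups, Pth was the single gene that passed between KO and WT implants. It had 0 reads in MKM2 and in the library labelled MKM1, and was at 19.8 and 17.7 CPM in MWM1 and MWM2, so it was at least 237-fold lower (adjusted p = 1.09e-05, limma with BH). From MKM2 alone the bound was 123-fold. There were 2346 genes at an unadjusted p under 0.05, and edgeR counted 0 with 2060 at an unadjusted p under 0.05. Lep was at 1191 ± 205 against 2282 ± 556 CPM (adjusted p = 0.332), Lepr at 18.9 ± 0.683 against 16.5 ± 3.09 CPM (adjusted p = 0.813), and Cfd at 14070 and 102 CPM in the library labelled MKM1 and in MKM2 against 1801 ± 579 CPM (adjusted p = 0.925). The median of all genes was 0.115, and 0.00545 with median-of-ratios scaling. The count was 250 (238 higher, 12 lower) without the libraries labelled EVFN1 and MKM1, where the KO side held MKM2 alone, assumed to vary like the other groups. It was 4 without MKM2 (Abcb1b higher, Nefl, Nefm and Pth lower), 2 without the library labelled MKM1 (Pth and Xist), 2 without MWM1 (Crisp1 and Pth) and 1 without MWM2 (Pth), and in each of these 4 fits 1 side held 1 library. Within the female groups 1021 genes passed, 165 higher and 856 lower in KO, and 2944 without the libraries labelled EVFN1 and MKM1 (1077 higher, 1867 lower). Under the naming rule these were Dhrs9, a retinol dehydrogenase, with 3.99 (SE 0.99), Vsig4 with 3.16 (SE 0.78) and Igf2bp2, an RNA binding protein, with 3.10 (SE 0.77), each at an adjusted p of 0.0448 (limma with BH), and Scgb1a1 with -6.38 (SE 1.38, adjusted p = 0.0279), Ighv1-26 with -5.74 (SE 1.03, adjusted p = 0.0136) and Igkv5-39 with -5.64 (SE 0.77, adjusted p = 0.00675). The last 2 are immunoglobulin segments and so uncertain. Lepr fell by 2.06 (SE 0.36, adjusted p = 0.0128), at 6.09 ± 0.07 against 27.4 ± 6.95 CPM. Lep was at 1685 ± 57.7 against 912 ± 151 CPM (adjusted p = 0.145) and Cfd at 97.5 ± 8.61 against 1320 ± 137 CPM (adjusted p = 0.315, and 0.00118 without the libraries labelled EVFN1 and MKM1). None of the 7 genes that passed here did so whichever library was left out, and with edgeR Ighv1-26 and Lepr passed. Median-of-ratios scaling gave 421 higher and 691 lower in the female groups, and moved the median of all genes from -0.198 to -0.0769. EdgeR counted 478 there, 242 higher and 236 lower. The count in the female groups was 492 without MKF1, 267 without MWF1, 230 without MWF2 and 4 without MKF2, among them Chga and Pth, again with 1 library on 1 side in each fit. Genes in these short lists were chosen after their values were seen.

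Male and female implant groups were then compared over both donor genotypes (4 against 4). Lymphocyte genes were lower in the male groups as a mean over both genotypes. Of 28 T and NK lymphocyte genes 18 fell, and 23 fell adjusted over the list alone (camera adjusted p = 2.67e-21, and adjusted p = 0.242 with an estimated correlation). Of 23 B and plasma cell genes 6 fell, and 20 fell adjusted over the list alone (camera adjusted p = 2.55e-10, and adjusted p = 0.401 with an estimated correlation). The mean of 4 lymphocyte markers was 141 and 88.7 CPM in MWF1 and MWF2, 23.05 in MKF1 and 0.859 in MKF2, against 1.43 and 5.05 in MWM1 and MWM2, 4.21 in MKM2 and 4.30 in the library labelled MKM1, so MKF2 did not follow. Xist was at 352 to 494 CPM in 3 of the 4 male libraries. The immunoglobulin segment Igkv3-2 had a log2 fold change of -5.71 (SE 0.98, adjusted p = 0.0204, limma with BH). Igkv3-4 and Ighv3-6 fell by 3.37 (SE 0.61, adjusted p = 0.0239) and 3.07 (SE 0.67, adjusted p = 0.0457), and such segments share reads, so single members are uncertain. The neutrophil attractant gene Cxcl1 rose by 1.63 (SE 0.36, adjusted p = 0.0458), the mitochondrial ferredoxin gene Fdx1 by 0.85 (SE 0.16, adjusted p = 0.0264) and Lurap1l by 0.87 (SE 0.16, adjusted p = 0.0253). None of Lep, Lepr and Cfd passed (adjusted p = 0.481, 0.47 and 0.602). In all 412 genes passed, 13 higher and 399 lower in the male groups, and 408 without the libraries labelled EVFN1 and MKM1 (88 higher, 320 lower), where T and NK genes that fell were 9 and B cell genes 3 (Bank1, Cd22 and Cd37, chosen after their values were seen). In that setting Cxcl1, Fdx1, Igkv3-4 and Ighv3-6 did not pass. EdgeR counted 79, with 4 higher (Abhd14b, Fst, Lurap1l and Retsat, chosen after their values were seen) and 75 lower, and the median of all genes was -0.0786 in limma and 0.04 in edgeR.

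The count between male and female implants depended on single libraries. It was 263 without MKM2, 147 without MWF2, 11 without MKF1, 5 without MWM1 (Crisp1 higher, Foxp3, Ighv1-52, Il17ra and Rinl lower), 4 without the library labelled MKM1 (Foxp3, Ighv1-52, Il17ra and Xist), 4 without MWM2 (Foxp3, Ighv1-52, Il17ra and Kcna3) and 0 in limma without MWF1, where 2448 genes had an unadjusted p under 0.05. A fit of these groups alone also gave 0 in limma, with 3241 genes at an unadjusted p under 0.05. Genes named here were chosen after their values were seen.

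Visceral and subcutaneous endogenous fat were compared as depots (6 against 2 libraries). The subcutaneous libraries were both of the male group ESM, while Xist was at 273 to 643 CPM in EVFY1, EVFY2 and EVFN2 and in the library labelled EVFN1 at 278 CPM, so the comparison of all visceral libraries did not separate depot and sex. EVM against ESM alone, groups that both had Ddx3y at 73.5 to 95.5 CPM, gave 50 genes, 35 of them among the 58 of the whole comparison. Myelin genes were lower in visceral fat. Prx was at 6.59 ± 2.26 CPM (n = 6) against 70.6 ± 18.9 (n = 2), a log2 fold change of -3.38 (SE 0.23, adjusted p = 0.00015, limma with BH), and Mbp, myelin basic protein, fell by 2.10 (SE 0.17, adjusted p = 0.000332). Drp2, a partner of periaxin, fell by 3.52 (SE 0.28, adjusted p = 0.000332) and Cldn19, a tight junction gene, by 3.89 (SE 0.27, adjusted p = 0.00015). Of 21 genes of satellite glia and Schwann cells 7 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 8.25e-20, and adjusted p = 0.0695 with an estimated correlation). Il1r2, a decoy receptor for interleukin-1, fell by 5.32 (SE 0.53, adjusted p = 0.00233) and the protocadherin gene Pcdh20 by 3.46 (SE 0.41, adjusted p = 0.00777). The limb patterning genes Shox2 and Tbx5 fell by 3.40 (SE 0.48) and 2.65 (SE 0.43), and in the patterning list of 33 genes 2 fell over all genes (camera adjusted p = 0.0768, and adjusted p = 0.693 with an estimated correlation). Ly6a, the progenitor antigen Sca-1, fell by 1.31 (SE 0.22, adjusted p = 0.0462). Among 22 adipocyte progenitor genes 4 fell adjusted over the list alone (Bmp7, Ly6a, Pi16 and Wnt2, camera adjusted p = 2.13e-08, and adjusted p = 0.322 with an estimated correlation). Bmp7, Pi16 and Wnt2 were chosen after their values were seen.

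Mesothelial genes were higher in visceral fat as a list, and so were single genes of epithelia. Myrf (chromosome 19, 10208272 to 10240748, minus strand), a transcription factor first described in myelin formation, was at 44.7 ± 17.3 against 0.227 ± 0.0797 CPM, a log2 fold change of 5.86 (SE 0.37, adjusted p = 0.00015, limma with BH). The collagen gene Col6a5 rose by 3.02 (SE 0.41, adjusted p = 0.0171), the cadherin gene Cdh11 by 2.90 (SE 0.34, adjusted p = 0.00777), Slpi, a secreted protease inhibitor of epithelia, by 3.59 (SE 0.59, adjusted p = 0.0447) and the tight junction gene Cgn by 3.00 (SE 0.46, adjusted p = 0.0292). Of 16 genes of mammary and glandular epithelium none passed over all genes and 3 rose adjusted over the list alone (Krt8, Krt18 and Prlr, the last chosen after its values were seen, camera adjusted p = 0.907), with adjusted p = 0.194 over all genes for Krt8 and 0.248 for Krt18. No mesothelial gene of 22 passed over all genes, and adjusted over the list alone 14 rose and 1 fell (Igfbp5, chosen after its values were seen, camera adjusted p = 9.58e-10, and adjusted p = 0.322 with an estimated correlation). Without the libraries labelled EVFN1 and MKM1, 14 mesothelial genes rose, with a camera adjusted p of 7.58e-27 and an adjusted p = 0.00147 with an estimated correlation. In that setting Wt1, a transcription factor of mesothelium, was at 63.8 ± 38.8 CPM (n = 5) against 0.142 ± 0.0398 (n = 2), a log2 fold change of 6.43 (SE 0.31, adjusted p = 2.94e-05). Upk3b had 1 read over both subcutaneous libraries, a ratio of 4940 (95% counting interval 886 to 195000, adjusted p = 2.35e-06), and Muc16, a mesothelial mucin, was at least 299-fold higher (adjusted p = 0.00304). The patterning genes Tbx15 (chromosome 3, 99240381 to 99354259, plus strand) and En1 were lower in visceral fat by -5.56 (SE 0.43, adjusted p = 0.000513) and -3.18 (SE 0.25, adjusted p = 0.000514). In the library labelled EVFN1, Wt1 was at 0.232 CPM and Upk3b at 0.058 CPM.

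Skin and interferon genes were lower in visceral fat by their lists. Krtdap, a protein of differentiating keratinocytes, fell by 2.58 (SE 0.37, adjusted p = 0.0182, limma with BH), the 1 call among 11 skin and hair follicle genes (Dmkn, Krt10 and Krtdap fell adjusted over the list alone, camera adjusted p = 3.57e-06, and adjusted p = 0.322 with an estimated correlation). None of 26 interferon response genes passed over all genes, and 5 fell adjusted over the list alone (Ifi27l2a, Ifit1, Irf7, Usp18 and Zbp1, camera adjusted p = 3.89e-14, and adjusted p = 0.322 with an estimated correlation). Dmkn, Krt10, Ifit1, Irf7, Usp18 and Zbp1 were chosen after their values were seen. The interferon-induced gene Ifi27l2a was at 271 ± 97.2 against 776 ± 219 CPM (adjusted p = 0.179). Lep was at 1159 ± 285 against 826 ± 439 CPM (adjusted p = 0.734), Lepr at 13.9 ± 12.5 against 6.03 ± 0.419 CPM (adjusted p = 0.565) and Cfd at 8236 ± 4759 against 10660 ± 3693 CPM (adjusted p = 0.913). Over all genes 58 passed, 16 higher and 42 lower in visceral fat, and edgeR counted 55. Without the libraries labelled EVFN1 and MKM1 215 passed, 102 higher and 113 lower. The count was 105 without EVM2, 33 without EVFY2, 32 without EVFN2, and 21 without ESM1 and 13 without ESM2, where 1 subcutaneous library was left. Of 15 genes named by the rule for this comparison that passed with all libraries, 6 passed whichever library was left out, which were Myrf, Il1r2, Cldn19, Drp2, Prx and Mbp.

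WT implants were compared with endogenous subcutaneous fat (4 against 2 libraries). Lymphocyte genes were higher in the implants. Trac (chromosome 14, 54220521 to 54224206, plus strand), the constant chain of the T cell receptor, was at 40.1 ± 43.4 CPM (SD, n = 4) in the implants and had a log2 fold change of 3.94 (SE 0.48, adjusted p = 0.011, limma with BH). Its levels in MWF1 and MWF2 were 88.7 and 64.8 CPM. Cd4, the helper T cell coreceptor, was at 46.4 ± 50.01 against 1.11 ± 0.445 CPM (n = 2) and rose by 3.59 (SE 0.49, adjusted p = 0.0125), Ccr7, a homing receptor of lymph nodes, by 3.37 (SE 0.48, adjusted p = 0.0133) and the B cell receptor genes Cd22 and Cd79b by 4.48 (SE 0.75, adjusted p = 0.0197) and 3.58 (SE 0.67, adjusted p = 0.0272). Of 28 T and NK lymphocyte genes 18 rose over all genes and 24 adjusted over the list alone (camera adjusted p = 2.5e-16, and adjusted p = 0.336 with an estimated correlation). Of 23 B and plasma cell genes 7 rose, and 18 adjusted over the list alone (camera adjusted p = 3.74e-09, and adjusted p = 0.336 with an estimated correlation). The mean of 4 lymphocyte markers was 141 and 88.7 CPM in MWF1 and MWF2 against 1.43 and 5.05 in MWM1 and MWM2 and 0.581 and 0.598 in ESM1 and ESM2, and thymus markers were at 86.6 CPM in MWF2. Of 16 mammary and glandular epithelium genes 2 rose (camera adjusted p = 0.00712, and adjusted p = 0.473 with an estimated correlation). Krt18 rose by 6.11 (SE 1.01, adjusted p = 0.0193), and Krt8, with 1 read over both subcutaneous libraries, had a ratio of 2490 (95% counting interval 446 to 98200, adjusted p = 0.0207). Among 27 complement genes 1 rose and 1 fell, the lectin pathway protease gene Masp1 with 2.46 (SE 0.40, adjusted p = 0.0186) and C7, a part of the membrane attack complex, with -3.18 (SE 0.58, adjusted p = 0.0255).

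Genes of neurons and myelin moved apart in this comparison. Nefh was at 9.24 ± 3.23 against 0.256 ± 0.0409 CPM, a log2 fold change of 3.63 (SE 0.52, adjusted p = 0.0133, limma with BH), and Nefl, Prph, a neurofilament of peripheral neurons, and Th rose by 2.58 (SE 0.48), 2.81 (SE 0.53) and 1.72 (SE 0.33). Of 19 sensory neuron genes 8 rose, and 13 adjusted over the list alone (camera adjusted p = 3.57e-06, and adjusted p = 0.336 with an estimated correlation). Mbp and Prx fell by 1.40 (SE 0.18) and 1.89 (SE 0.25), both with an adjusted p of 0.011. Of 21 genes of satellite glia and Schwann cells 3 fell, and adjusted over the list alone 7 fell and 2 rose (Kcnj10 and Ngfr, chosen after their values were seen, camera adjusted p = 0.000335, and adjusted p = 0.336 with an estimated correlation). Gfap (chromosome 11, 102887336 to 102900912, minus strand), a filament of astrocytes and glia, rose by 7.28 (SE 1.57, adjusted p = 0.0434). Lung transcripts moved with these genes. Sftpc (chromosome 14, 70520949 to 70524081, minus strand), a surfactant protein, was at 119 ± 55.4 CPM in WT implants with 0 reads in subcutaneous fat, at least 1390-fold higher (adjusted p = 0.0193), and Scgb1a1 rose by 7.04 (SE 1.20, adjusted p = 0.0208). The keratinocyte genes Krtdap and Dmkn fell by 2.75 (SE 0.39) and 2.67 (SE 0.54), with a camera adjusted p of 0.0367 for the skin list, and adjusted p = 0.502 with an estimated correlation. Rasd1, a small G protein induced by glucocorticoids, fell by 2.78 (SE 0.48, adjusted p = 0.0228), Pcdh20 by 2.79 (SE 0.44, adjusted p = 0.0168) and Il1r2 by 2.66 (SE 0.56, adjusted p = 0.0407).

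Lepr rose in WT implants against subcutaneous fat, at 21.95 ± 7.71 against 6.03 ± 0.419 CPM (log2 fold change 1.72, SE 0.31, adjusted p = 0.0255, limma with BH). Lep was at 1597 ± 858 against 826 ± 439 CPM (adjusted p = 0.147). Cfd was at 1560 ± 442 against 10660 ± 3693 CPM, a log2 fold change of -2.77 with SE 1.96 and adjusted p = 0.469 with all libraries, and SE 0.35 and adjusted p = 0.00307 without the libraries labelled EVFN1 and MKM1, which enter this test only through the shared spread. Xist rose by 9.54 (SE 1.25, adjusted p = 0.011) and was at 554 ± 142 CPM in the implants and 0.255 ± 0.281 CPM in ESM. Over all genes 444 passed, 395 higher and 49 lower, and 1861 without both libraries (1534 higher, 327 lower). Median-of-ratios scaling gave 362 higher and 99 lower and moved the median of all genes from 0.141 to 0.031. EdgeR counted 68, 40 higher and 28 lower. The count was 225 without MWF1, 134 without MWF2, 72 without MWM2, 70 without MWM1, 5 without ESM2 (Chga, Cxcr4, Pth and Wnt4 higher, Ddn lower) and 4 without ESM1 (Bicdl1, Cxcr4 and Pth higher, Krt10 lower), genes chosen after their values were seen. Each of the 28 genes named by the rule for this comparison that passed with all libraries lost its call when ESM1 or ESM2 was left out, which leaves 1 subcutaneous library.

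WT implants were compared with visceral fat next (4 against 6 libraries). Skeletal muscle genes were higher in the implants. Casq1, the calcium store protein of fast muscle, was at 213 ± 183 CPM (n = 4) against 3.07 ± 1.87 (n = 6), a log2 fold change of 5.60 (SE 1.11, adjusted p = 0.0176, limma with BH). The muscle genes Cacng1 and Eno3 rose by 4.28 (SE 0.88, adjusted p = 0.0195) and 5.13 (SE 1.10, adjusted p = 0.0227), and Pvalb, a calcium buffer of fast fibres, by 7.21 (SE 1.62, adjusted p = 0.0264). The giant sarcomere protein gene Ttn rose by 7.92 (SE 2.17, adjusted p = 0.0469), Xirp2 by 7.53 (SE 1.83, adjusted p = 0.0341), and the troponin genes Tnnt3 and Tnni2 by 7.45 (SE 2.06) and 7.27 (SE 1.97). Of 24 muscle genes 14 rose, and 21 adjusted over the list alone (camera adjusted p = 5.89e-08, and adjusted p = 0.535 with an estimated correlation). The mean of 4 muscle markers was 578 (MWF2) to 8160 CPM (MWF1) in the WT implants, 3306 in ESM2 and 23.04 in ESM1. Of 28 T and NK lymphocyte genes 19 rose, and adjusted over the list alone 23 rose and 1 fell (Ncr1, chosen after its values were seen, camera adjusted p = 3.15e-10, and adjusted p = 0.535 with an estimated correlation). Foxp3, Cd247, Icos and Ccr7 rose by 1.5 (SE 0.18), 1.82 (SE 0.27), 1.6 (SE 0.24) and 2.38 (SE 0.36), with adjusted p of 0.00318 to 0.00691. Of 23 B and plasma cell genes 11 rose, and 19 adjusted over the list alone (camera adjusted p = 4.15e-06, and adjusted p = 0.535 with an estimated correlation). Cr2 rose by 3.04 (SE 0.51, adjusted p = 0.0093), Ighm by 1.76 (SE 0.35, adjusted p = 0.0181), Cd79b by 2.06 (SE 0.50, adjusted p = 0.0335) and the Fc receptor-like gene Fcrla by 1.85 (SE 0.46, adjusted p = 0.0375). The lymphocyte marker mean was 141 and 88.7 CPM in MWF1 and MWF2, while 1.43 and 5.05 CPM in MWM1 and MWM2 lay within the 1.10 to 5.08 CPM of the 6 visceral libraries. Foxp3 was likewise at 14.1 and 12.3 CPM in MWF1 and MWF2, at 0.517 and 0.565 in MWM1 and MWM2 and at 0.302 to 1.43 CPM in visceral fat, and thymus markers were at 86.6 CPM in MWF2.

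Nerve genes were also higher in WT implants than in visceral fat. Prx was at 18.6 ± 3.33 against 6.59 ± 2.26 CPM, a log2 fold change of 1.49 (SE 0.18, adjusted p = 0.00343, limma with BH), and Cnp rose by 0.91 (SE 0.11, adjusted p = 0.00318). Of 21 genes of satellite glia and Schwann cells 12 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell (in both Ednrb, chosen after its values were seen, camera adjusted p = 9.42e-06, and adjusted p = 0.535 with an estimated correlation). Of 19 sensory neuron genes 12 rose, and 13 adjusted over the list alone (camera adjusted p = 3.36e-08, and adjusted p = 0.535 with an estimated correlation). Nefh rose by 3.76 (SE 0.39, adjusted p = 0.0024), Nefl by 3.08 (SE 0.36, adjusted p = 0.0031) and Avil by 1.73 (SE 0.16, adjusted p = 0.00222). Th had 1 read over the 6 visceral libraries, a ratio of 183 (95% counting interval 32.1 to 7280, adjusted p = 0.00378). The mean of 3 parathyroid markers was 19.9 to 36.5 CPM in these implants. Of 18 brown and beige fat genes 5 rose, and 8 adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.535 with an estimated correlation), among them the respiratory genes Cox8b with 3.16 (SE 0.50, adjusted p = 0.008) and Cox7a1 with 2.60 (SE 0.51, adjusted p = 0.0168), and the proton channel gene Otop1 with 3.13 (SE 0.84, adjusted p = 0.0448). Cox8b and Cox7a1 were highest in MWF1, the library with the highest muscle markers, and Cox7a1 was at 16.3 CPM in ESM2 and 2.89 in ESM1, where muscle markers were at 3306 and 23.04 CPM. The patterning list of 33 genes had 4 higher and 1 lower, with a median of -0.585 over members that moved both ways (camera adjusted p = 0.00434, and adjusted p = 0.535 with an estimated correlation). Tbx15 and Shox2 rose by 5.01 (SE 0.79, adjusted p = 0.00791) and 2.18 (SE 0.38, adjusted p = 0.0108), and Hoxc4 fell by 1.02 (SE 0.27, adjusted p = 0.0432). The others that passed in these 2 lists were Elovl3 and S100b, and Irx1 and Tbx5, of which Elovl3 and Irx1 were chosen after their values were seen.

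Mesothelial genes were lower in WT implants than in visceral fat, as were some macrophage genes. Upk3b was at 0.162 ± 0.0995 against 118 ± 77.7 CPM, a log2 fold change of -6.33 (SE 1.69, adjusted p = 0.0437, limma with BH), and -7.67 (SE 0.21, adjusted p = 1.04e-06) without the libraries labelled EVFN1 and MKM1. Upk1b, Bnc1 and Nkain4 fell by 4.09 (SE 1.09), 3.34 (SE 0.87) and 2.53 (SE 0.63). Of 22 mesothelial genes 5 fell (these and Rspo1), and adjusted over the list alone 9 fell and 3 rose (Igfbp5, Krt8 and Krt18, camera adjusted p = 5.2e-05, and adjusted p = 0.535 with an estimated correlation). Without both libraries 15 fell and 1 rose (Krt18), with an adjusted p = 0.0134 with an estimated correlation. Igfbp5, Krt8, Krt18 and Rspo1 were chosen after their values were seen. Of 25 macrophage genes 4 fell (camera adjusted p = 0.00011, and adjusted p = 0.535 with an estimated correlation), which were Mertk, a receptor for uptake of dying cells, with -0.95 (SE 0.18, adjusted p = 0.0137), Siglec1 with -1.43 (SE 0.27, adjusted p = 0.0151), Folr2 with -1.42 (SE 0.36, adjusted p = 0.0385) and Csf1r with -0.91 (SE 0.25, adjusted p = 0.0461), and the same number fell adjusted over the list alone. Without both libraries 5 macrophage genes fell (these and Cd163) and 2 rose (Cx3cr1 and Itgax), with a median log2 fold change of -0.0263 and a camera adjusted p of 0.0348, and adjusted p = 0.581 with an estimated correlation. Cd163, Cx3cr1 and Itgax were chosen after their values were seen. The collagen gene Col6a5 fell by 3.02 (SE 0.33, adjusted p = 0.00264), Ccbe1, a factor of lymphatic vessel growth, by 2.41 (SE 0.24, adjusted p = 0.00222), Rasd1 by 2.35 (SE 0.36, adjusted p = 0.00693), the GABA receptor gene Gabra3 by 2.02 (SE 0.38, adjusted p = 0.0143) and the carboxypeptidase gene Cpz by 1.95 (SE 0.37, adjusted p = 0.0146). Lepr rose by 0.95 (SE 0.23, adjusted p = 0.0354) and Lep was at 1597 ± 858 against 1159 ± 285 CPM (adjusted p = 0.346). Cfd was at 1560 ± 442 against 8236 ± 4759 CPM (adjusted p = 0.531), and without both libraries it had a log2 fold change of -2.70 (SE 0.28, adjusted p = 0.000643).

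Between WT implants and visceral fat 1735 genes passed, 1443 higher and 292 lower in the implants, and 4001 without the libraries labelled EVFN1 and MKM1 (2842 higher, 1159 lower). EdgeR counted 1387, 840 higher and 547 lower. Median-of-ratios scaling gave 1256 higher and 587 lower, and the median of all genes was 0.0897 in limma and -0.0112 in edgeR. Of the muscle genes named, Ttn, Tnnt3 and Tnni2 did not pass without both libraries (adjusted p = 0.0504, 0.0566 and 0.0511, limma with BH). The count was 1050 without EVFY2, 1020 without MWF2, 991 without EVFN2, 833 without EVM2, 668 without MWF1, 637 without EVFY1, 311 without MWM2 and 296 without MWM1. Of 44 genes named by the rule for this comparison that passed with all libraries, 15 passed whichever library was left out, among them Avil, Nefh, Tbx15, Foxp3, Cox8b, Col6a5 and Ccbe1.

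**Figure D2:**
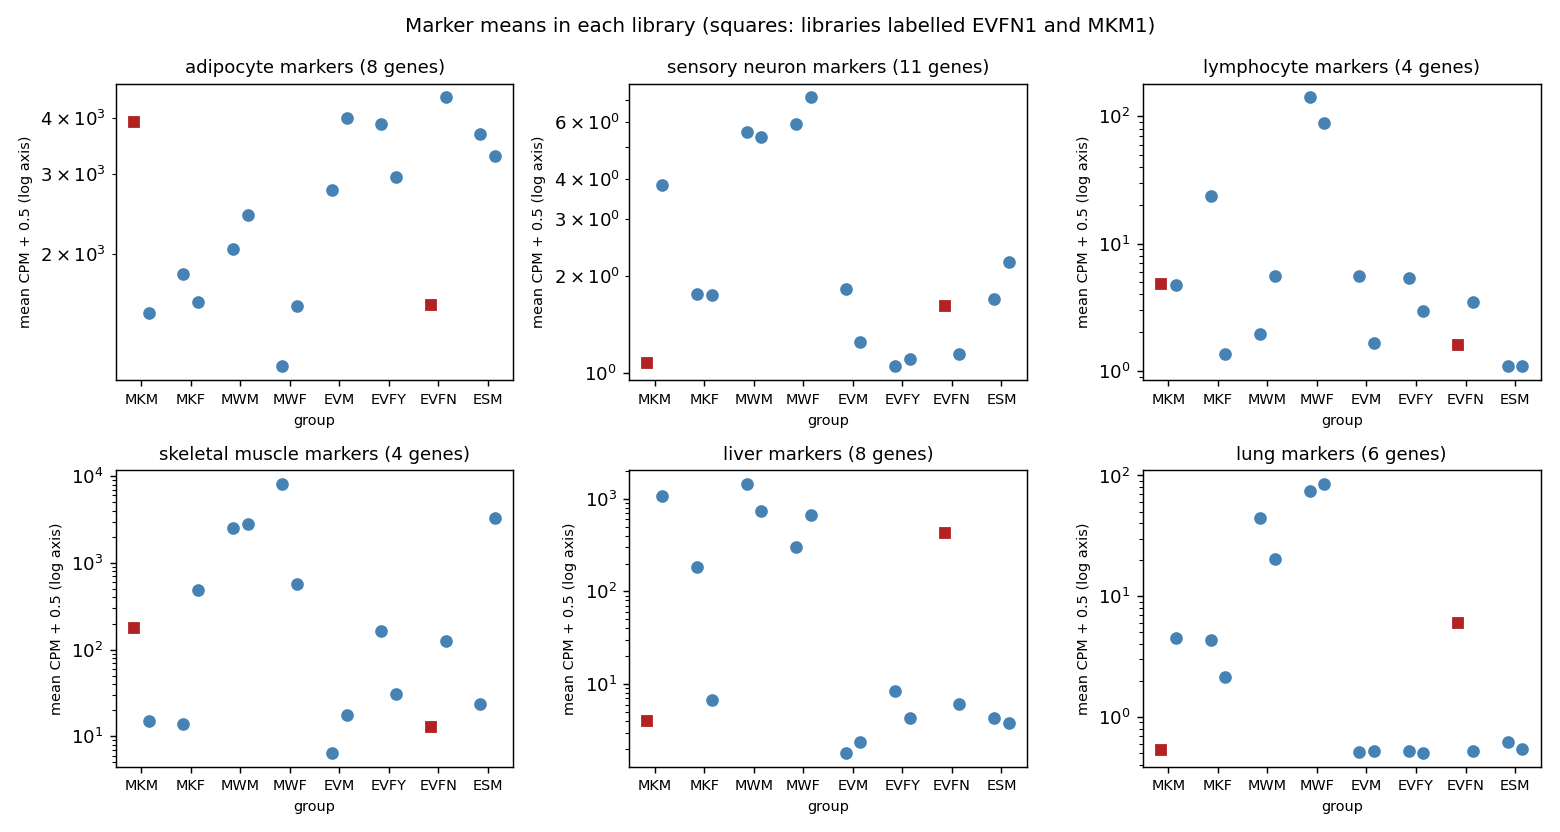
Mean CPM + 0.5 (log axis) of the marker genes of adipocytes (8 genes), sensory neurons (11), lymphocytes (4), skeletal muscle (4), liver (8) and lung (6) in each library, by group code on the x axis. Red squares are the libraries labelled EVFN1 and MKM1 and blue circles the others. Lymphocyte markers lie at 141 and 88.7 CPM in MWF1 and MWF2, and lung markers at 19.97 to 84.7 CPM in the 4 WT implants.

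The visceral codes EVFY and EVFN were compared by code (2 against 2 libraries). Limma counted 0 genes, with 806 at an unadjusted p under 0.05, and edgeR counted 0 with 1216 at an unadjusted p under 0.05. Without the libraries labelled EVFN1 and MKM1 limma also counted 0, with 414 at an unadjusted p under 0.05. Genes of the mesothelium list had a camera adjusted p of 3.12e-07 for higher levels in EVFY, and an adjusted p = 0.731 with an estimated correlation. Wt1 was at 83.9 and 118 CPM in EVFY1 and EVFY2, at 60.4 CPM in EVFN2 and at 0.232 CPM in the library labelled EVFN1. Of the single libraries left out, EVFY1 gave 6 genes, all higher in EVFY2, which then stood alone for its side, and EVFN2 gave 1, Cyp21a1, an adrenal steroid enzyme gene chosen after its values were seen, with the library labelled EVFN1 alone for its side. A lone library is assumed to vary like the other groups. None of Lep, Lepr and Cfd passed between EVFY and EVFN (adjusted p = 0.841 for each, limma with BH).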

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

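The tests of exchanged labels, of mixed RNA, of animals that differ from their group, of organ material and of the adipocyte share were chosen only after the results were seen, while the scaling of Cfd and the regrouping of libraries were set before, except those without a library labelled EVFN1 or MKM1, which were chosen after seeing the data. A library was taken as far from the others when its gap to the nearest of them, as a share of the whole range of 4 or 6 libraries, was above Dixon's critical value. Chance does this in about 1 of 20 groups of values. It occurred for 13 of 46 genes tested in the KO implants, 13 of 66 in visceral fat and 6 of 91 in the WT implants. Genes named because they passed without the libraries labelled EVFN1 and MKM1 are among those tested, which favours gaps at these 2 libraries, so their share cannot be set against chance.

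In the KO implants the library labelled MKM1 was the lowest for the macrophage and osteoclast genes Adgre1 (gap 0.882 of the range), Atp6v0d2 (0.981), Cd68 (0.878), Gpnmb (0.971), Tm4sf19 (0.955) and Trem2 (0.957), and for Myh15 (0.945). It was the highest for the adipocyte genes Adrb3 (0.925), Car3 (0.885), Cfd (0.975) and Retn (0.941). MKM2 was the highest for the epithelial gene Grhl2 (0.861), at 0.56 CPM, and MKF2 for Pth (1), with the 2 reads of these implants. In visceral fat the library labelled EVFN1 was the lowest for the mesothelial and epithelial genes Bnc1 (0.734), Krt7 (0.63), Muc16 (0.688), Nkain4 (0.781), Upk1b (0.775), Upk3b (0.8) and Wt1 (0.657), and for Cfd (0.849). It was the highest for the patterning genes En1 (0.735) and Tbx15 (0.81), the macrophage gene Folr2 (0.667) and the neurofilament gene Nefl (0.722). EVM1 held the single visceral read of Th (1). In the WT implants MWF1 was the lowest for Krt18 (0.885), and MWF2 was the highest for Adrb3 (0.89), Bnc1 (0.874) and Xist (0.883), MWM1 for Cpz (0.863) and MWM2 for Th (0.847). With all 16 libraries the KO difference varied with sex for 217 genes, with an adjusted p (limma, BH) of 0.0378 for Cd247, 0.0306 for Cnp and Foxp3 and 0.0401 for Ltbp3. The count was 0 with edgeR, the pseudocount of 0.1 or only the compared groups. The male label MKM1 is also in doubt, with Xist at 352 CPM and Ddx3y at 0. MWM1 and MWM2 held both, which decides nothing, as host and donor may differ in sex.

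The libraries labelled EVFN1 and MKM1 stood apart from the other library of their group. Mixed RNA of the 2 samples is argued against, because 72 genes high in the library labelled EVFN1 stood at a median of 0.0678% of that level in the library labelled MKM1, and 5 genes at 0.029% the other way. A male animal that merely differed from its group is argued against for the library labelled MKM1 by its 2 reads from 4 Y-linked genes, and tissue of 1 differing animal for the library labelled EVFN1 by Ddx3y at 29.3 CPM beside Xist at 278 CPM, although MWM1 and MWM2 held both transcripts as well. Exchanged labels are a candidate explanation, since 2 of the 2 libraries lay closer to the remaining library of the other label than to that of their own. Organ markers bear on this too. The library labelled EVFN1 had liver and lung markers at 424 and 5.49 CPM. The other endogenous fat libraries had them at 1.30 to 7.96 and 0 to 0.113 CPM. In the library labelled MKM1 they were at 3.45 and 0.0276 CPM. The other KO implants had lung markers at 1.65 to 4.03 CPM, and liver markers at 1062 (MKM2), 181 (MKF1) and 6.30 CPM (MKF2). Other samples of the study that are not analysed here, and a difference between the animals that the labels do not record, stay open.

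Transcripts of liver, lung and parathyroid appeared in all WT implants, and those of thymus, thyroid or pancreatic islets mainly in some. Material of 1 common source that brought both liver and lung transcripts is argued against, because the ratio of their markers was 4.05 (MWF1), 7.82 (MWF2), 33.1 (MWM1) and 36.8 (MWM2), a range of 9.1-fold. A common source of each group alone stays open, as these ratios were closer within a group. So does 1 common source of parathyroid and lung transcripts, whose ratio ranged over 2.41-fold. Tissue of other organs inside single implants is not decided. Of 25 markers 84% were highest in the library where most of their organ's markers were, which any source of varying amount would give. A candidate source is organ tissue carried along with embryonic fibroblasts, which no sample here can test. Donor genotype was not separated from the preparation of the cells, so the lower lung and parathyroid markers in the KO implants may follow either. In MKM2 liver, islet and thymus markers, at 1062, 10.5 and 6.18 CPM, were each above 3 of the 4 WT implants.

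Cfd was lower in KO than in WT implants without the libraries labelled EVFN1 and MKM1 (log2 fold change -3.92, SE 0.32, adjusted p = 0.000339, limma with BH), the setting of both tests here, itself chosen after seeing the data. Cfd did not pass with only the library labelled MKM1 left out (adjusted p = 0.137) or with all 16 (adjusted p = 0.452). A lower adipocyte share, seen evenly over its genes, is argued against. The other 23 white adipocyte genes had a median log2 fold change of 0.072 (median absolute deviation 0.493). But of all 24, 6 fell and 1 rose, and Adrb3, Retn and Car3 fell too. Scaling is argued against by a log2 fold change of -3.92 (SE 0.35, adjusted p = 0.000345, limma with BH) with median-of-ratios scaling. The lower level could follow the leptin genotype of the donor cells, as a hypothesis, or the macrophage content or preparation of these implants, and the design does not separate them.

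Other splits of the same libraries were run in fits of the compared libraries alone. Between KO and WT implants 132 genes passed, and 1 of the 35 splits, the real one, gave as many (highest other 0). Between WT implants and visceral fat 1151 passed, and 1 of 100 drawn splits gave as many, the highest other being 650, for EVFN2, EVFY1, EVFY2 and EVM2 against the rest. Chance can be excluded for these 2 counts only if the libraries are separate units, which the labels do not state. Without the library labelled MKM1 1805 genes passed between KO and WT implants, and 1 of the 35 splits gave as many (highest other 1). Without the library labelled EVFN1 1890 passed between WT implants and visceral fat, and 1 of 100 drawn splits gave as many, with 148 as the highest other. These libraries were left out because they stood apart from their own side, which favours the real split, so both of these tests decide nothing about chance. Between male and female implants 0 passed in such a limma fit. Any split gives as many (35 of 35), so chance was not tested. The highest other split, with 132 genes, was that of KO against WT, which is a structure of these libraries.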

How the results depend on the processing

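All alternatives named here were set in advance, except the fit without the libraries labelled EVFN1 and MKM1, which was chosen only after the results were seen. Counts are genes past the threshold in limma unless edgeR is named, and the cause of each change was not tested. Of 184 results on named genes, 145 kept their direction and side of the threshold without both libraries, 27 passed in addition, 9 no longer passed and 3 changed direction. With edgeR 123 kept both and 60 no longer passed, and with median-of-ratios scaling these numbers were 179 and 3. With the pseudocount of 0.1 they were 144 and 40, with the pseudocount of 2 179 and 2, without a filter 175 and 8, with array weights 170 and 9, and with only the compared groups in the fit 142 and 37. Over the left-out libraries, 24 of 128 named genes past the threshold stayed past it every time. Depth limits genes near 0.039 to 0.061 CPM, the worth of 1 read.

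Between KO and WT implants the count of 309 became 77 with the pseudocount of 0.1, 611 with the pseudocount of 2, 523 without a filter, 954 with array weights, 176 with edgeR, 112 with only the compared groups and 1935 without both libraries. Leaving out 1 library gave 2 to 307. For the difference by sex, 217 became 0 with the pseudocount of 0.1 (3140 at an unadjusted p under 0.05), 421 with the pseudocount of 2, 339 without a filter, 71 with median-of-ratios scaling, 0 with edgeR (2852 at an unadjusted p under 0.05), 0 with only the compared groups (3593 at an unadjusted p under 0.05) and 101 without both libraries, and leaving out 1 library gave 0 to 283. In the male groups 1 became 8 with the pseudocount of 2, 12 without a filter, 2 with median-of-ratios scaling (Ces3b and Pth, chosen after their values were seen), 0 with edgeR (2060 at an unadjusted p under 0.05), 0 with only the compared groups (1926 at an unadjusted p under 0.05) and 250 without both libraries, and leaving out 1 library gave 1 to 4. In the female groups 1021 became 602 with the pseudocount of 0.1, 3658 with array weights, 478 with edgeR, 2177 with only the compared groups and 2944 without both libraries, and leaving out 1 library gave 4 to 492. Between male and female implants 412 became 205 with the pseudocount of 0.1, 79 with edgeR and 0 with only the compared groups (3241 at an unadjusted p under 0.05), and leaving out 1 library gave 0 to 338.

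Between visceral and subcutaneous fat 58 became 94 without a filter, 38 with array weights, 13 with only the compared groups and 215 without both libraries. EVM against ESM alone gave 50, and EVM and EVFY against ESM gave 45. Both kept all 16 libraries in the fit, so EVFN still entered the shared spread. Leaving out 1 library gave 13 to 105. Between WT implants and subcutaneous fat 444 became 273 with the pseudocount of 0.1, 68 with edgeR, 1847 with only the compared groups and 1861 without both libraries, and leaving out 1 library gave 4 to 225. Between WT implants and visceral fat 1735 became 4001 without both libraries, and leaving out 1 library gave 296 to 2390. The count was 1237 against EVM and EVFY, again with EVFN in the fit. Between EVFY and EVFN leaving out 1 library gave 0 to 6.

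The replicate number was also fitted as a block, although libraries share only a number. Between groups, the deviations of libraries with the same number correlated by -0.467 to 0.277 over the 6 pairs of implant groups, with 2 of them above 0.1, by -0.202 to 0.2 over the 6 pairs of endogenous groups, by -0.443 to 0.131 between WT implants and ESM and by -0.252 to 0.275 between the WT implant and visceral groups. With the replicate block 89 genes passed between KO and WT implants, 90 for the difference by sex, 38 between visceral and subcutaneous fat, 284 between WT implants and subcutaneous fat and 1099 between WT implants and visceral fat. Of the 184 named-gene results 144 kept their direction and side with the block and 40 no longer passed.

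Direction changed for Lep between KO and WT implants, from a log2 fold change of -0.0165 to 0.0719 without both libraries, with a range of -0.142 to 0.109 when 1 library was left out (above 0 without MKF1, MWF2, MWM2 or the library labelled MKM1). It changed for Lep between visceral and subcutaneous fat to -0.0123 without ESM2, in a range up to 1.12, and for Lepr there to -0.36 with EVM against ESM alone. For Cfd it changed in the difference by sex to -0.342 without both libraries (-0.342 to 6.76 with 1 library left out, below 0 without the library labelled MKM1), in the male groups to 1.87 with edgeR (-4.09 to 3.00, above 0 without MKM2) and between EVFY and EVFN to -0.401 without both libraries (-0.401 to 6.82, below 0 without the library labelled EVFN1). None of these passed. Without both libraries, of 203 tests of a list 24 passed in addition, 15 no longer passed and 139 kept their direction and side. A further 18 changed direction but passed in neither fit, and 7 that passed in at least 1 fit changed direction. These were mesothelium (camera adjusted p = 0.00852) and the sex chromosome check (adjusted p = 0.00852) between KO and WT implants, the sex chromosome check by sex (adjusted p = 0.00116), and between EVFY and EVFN the cell cycle (adjusted p = 4.15e-05), cholesterol synthesis (adjusted p = 0.906), endothelium (adjusted p = 0.00414) and macrophage lists (adjusted p = 0.121). With an estimated correlation 104 of the 203 no longer passed and 99 kept their side.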

Other observations

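The lists below were set before the data were examined, and all were tested again without the libraries labelled EVFN1 and MKM1, a setting chosen only after the results were seen. In that setting further lists are given here for WT implants against visceral fat. Of 25 cell cycle genes 11 rose in the implants, and 20 rose adjusted over the list alone (camera adjusted p = 2.71e-05, and adjusted p = 0.581 with an estimated correlation). With all libraries none passed, either over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.0293, and adjusted p = 0.765 with an estimated correlation. The ribonucleotide reductase gene Rrm2 was at 61.8 CPM and the cyclin gene Ccnb1 at 17.2 CPM in MWF2, where thymus markers were at 86.6 and lymphocyte markers at 88.7 CPM. Ccnb1 was at 1.41 and 1.30 CPM in MWM1 and MWM2, within the 1.06 to 3.96 CPM of the 5 visceral libraries of this setting. Both genes were chosen after their values were seen. Of 21 genes of cholesterol synthesis 12 rose, against 3 with all libraries, and 15 rose adjusted over the list alone (camera adjusted p = 4.92e-05, and adjusted p = 0.581 with an estimated correlation). Of 24 endothelial genes 10 fell, against 2 with all libraries (camera adjusted p = 1.5e-07, and adjusted p = 0.488 with an estimated correlation). Of 24 white adipocyte genes 14 fell and 1 rose, against 1 that fell with all libraries (camera adjusted p = 5.98e-08, and adjusted p = 0.488 with an estimated correlation). Of 23 genes of de novo lipogenesis 1 rose and 1 fell (camera adjusted p = 0.135), and of 28 genes of mitochondrial respiration 2 rose (camera adjusted p = 0.178).

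None of 25 immediate early genes, which respond within minutes to stimulation or to handling of tissue, passed over all genes between EVFY and EVFN in limma. In the setting without both libraries, where EVFN2 alone stood for its side and was assumed to vary like the other groups, 14 were lower in EVFY adjusted over the list alone, and camera gave an adjusted p of 1.02e-27, with adjusted p = 0.0657 with an estimated correlation. With all 16 libraries 1 was lower adjusted over the list alone (camera adjusted p = 0.000239, and adjusted p = 0.731 with an estimated correlation). Albumin (Alb, of the liver) was at 6958 CPM in MWM1, 5622 in MKM2, 3481 in MWM2 and 3386 in MWF2, and at 26.7 CPM in the library labelled MKM1. The mean of 2 thyroid markers was 105 CPM in MWF2 and that of 3 pancreatic islet markers 13.4 CPM in MWM1 and 10.5 in MKM2.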
